A study of Mus musculus with 12 samples.

How the data were processed

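Total RNA of J774.1 cells was isolated with a column kit and sequenced as Illumina libraries, per the labels. The 12 libraries were grouped by the genotype and the treatment that the labels give. This made 6 groups of 2 libraries: WT, Rictor-KO and GATA3-KO cells, each with DMSO or with isorhamnetin at 10 µM for 6 h. Nothing in the labels says that the replicates came from separate cultures, so p-values measure the spread between these libraries, which may be technical. The labels name 1 line per knockout, so the effect of a knockout and the history of its cell line cannot be told apart.

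The authors deposited counts of reads per gene for each library, split into exon, intron and uniquely mapped reads, with 25683 genes in each table. Gene identifiers and positions follow GRCm38, the build named in the submitters' processing notes. The aligner and the counting program were not given in the sources used here. Of the identifiers, 25640 (99.8%) were found in the GENCODE M21 annotation, and 25431 of those (99.2%) stood at the same position. The tables list 3742 genes without an annotated exon, whose exon counts are 0 by construction. Of 12371 gene and library values of 1 to 4 exon reads, 81.3% were even, with 6440 values of 2 and 1607 of 1. Both reads of a pair thus appear to be counted, which makes counting intervals and floors in reads optimistic. The authors also deposited tables of log2 fold changes, p-values and false discovery rates for isorhamnetin against DMSO in each genotype. The test behind the authors' deposited p-values was not given in the sources used here, and these tables were only described.

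Total exon reads per gene were analysed with edgeR 4.0.16 in R 4.3.3. Of 15156 genes with an exon read, 11808 passed filterByExpr on the 6 groups and 3348 did not. Libraries were scaled with TMM, whose factors were 0.912 and 0.913 for the WT DMSO libraries and between 0.992 and 1.05 for the others. All 12 libraries were fitted in 1 model with a mean per group. The robust quasi-likelihood F test, which takes changes in both directions, was used with 6 residual degrees of freedom and a median of 8.08 prior degrees of freedom. The common biological coefficient of variation was 0.11. P-values were adjusted by the Benjamini-Hochberg method over the 11808 genes within each of 9 contrasts, and 0.05 was the threshold. The contrasts were isorhamnetin against DMSO in each genotype, their mean, each knockout's response minus that of WT, each knockout against WT under DMSO, and the knockouts against each other. "Rose", "fell", "higher" and "lower" are used of genes past that threshold. Errors of log2 fold changes are standard errors (SE) from that fit, with n = 2 libraries per group. Levels are CPM, which are counts scaled to a common library total with TMM, as mean and SD.

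The comparisons, the rule for naming genes, the gene lists and most alternatives were fixed before the data were examined. The naming rule takes Rictor, Gata3 and the 10 genes with the largest positive and the 10 with the largest negative fold change past the threshold. Those genes needed a mean log2 CPM of at least 1, a named symbol and, between 2 groups, CPM values that do not overlap. It also takes up to 4 members of each described gene list, by smallest p. Members named because at most 5 moved in a direction were chosen after their values were seen. The rule names some genes with few reads. Where a group had 0 reads, the fold is a lower bound against 3 reads over that group's libraries, a floor of 0.0374 to 0.0431 CPM under DMSO. Where it had 1 to 3 reads, a ratio of the 2 groups is given with its 95% counting interval. These intervals and floors cover counting error only. Genes with under 90% unique reads are marked as uncertain.

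Of 41 gene lists, 34 with at least 5 tested members were tested with camera of limma 3.58.1 at a preset inter-gene correlation of 0.01. Their p-values were adjusted by the Benjamini-Hochberg method within a contrast. Camera was repeated with an estimated correlation, and fry was run beside it. Of 124 list calls, 8 held with the estimated correlation. These were the NRF2 targets in all 3 genotypes and in the mean, the interferon-stimulated genes in WT and in the mean, and the metal response list in Rictor-KO and in the mean. Members past the threshold were counted over all genes tested and adjusted over the list alone. Members that lists share count in each. Of the genes that the naming rule takes, 1 is not reported here.

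On simulated counts with known changes, isorhamnetin in WT recovered 62% of 50 genes changed 1.5-fold, 86% of those changed 2-fold and 88% of those changed 4-fold. Of 171 calls, 7 were false. False calls were 9 of 193 for the mean over genotypes, 10 of 170 for Rictor-KO against WT and 13 of 154 for the response of Rictor-KO minus that of WT. At 1.5-fold these contrasts recovered 82%, 58% and 36%. In this 1 simulated data set per contrast, the difference in response had the most false calls and missed the most small changes. Such single draws do not settle whether its rate of false calls is higher. No list of 40 without a simulated effect was called, but the simulated genes varied independently of each other. That check thus cannot tell whether the preset correlation is too low for the real lists. Replicates were compared by a chi-square statistic over genes, which was 8.12 to 38 times its degrees of freedom within the 6 groups, so no library was counted as a duplicate.

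Alternatives chosen in this way were DESeq2 size factors as edgeR computes them, the DESeq2 1.42.0 Wald test, no filter, a threshold of 1 on the absolute log2 fold change, reads with introns included, unique exon reads, each library left out in turn, only the groups compared, and a replicate block. Others were chosen after seeing the data: the knockout lines only, crossed WT replicate numbers, separate WT DMSO libraries for isorhamnetin and knockout effects, separate WT isorhamnetin libraries for the knockouts under isorhamnetin, and genes outside chromosome 17. Where a left-out library leaves 1 in its group, that library is assumed to vary like the other groups. Intron reads were tested in the same model for 11450 genes. Agreement of fold changes that share WT DMSO libraries was compared with 20 simulations of unchanged groups. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 served for reading, checks and plots.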

Results

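RNA levels were measured in J774.1 cells, a mouse macrophage-like line, as reads per gene. Unedited cells (WT) and lines labelled as knockouts of Rictor or of Gata3 were kept for 6 h with DMSO or with isorhamnetin at 10 µM. Isorhamnetin is a methylated plant flavonol. Rictor is the defining subunit of the kinase complex mTORC2, and Gata3 encodes a zinc finger transcription factor best known in T lymphocytes. Each of the 6 groups held 2 libraries, 12 in all. Exon reads numbered 37313642 and 38991173 in the WT libraries with DMSO, and 39361017 and 38118553 in those with isorhamnetin. In Rictor-KO they numbered 35671457 and 38774368 with DMSO, and 38685944 and 38593807 with isorhamnetin. In GATA3-KO they numbered 39045328 and 41475472 with DMSO, and 53099804 and 43542173 with isorhamnetin. Mitochondrially encoded transcripts took 0.46% to 0.61% of exon reads in the GATA3-KO libraries and 0.85% to 1.23% in the others. The replicates may be technical, and each knockout is 1 line, so knockout and clone cannot be told apart.

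The targeted genes were examined first, in every library. Rictor (ENSMUSG00000050310, chromosome 15, 6708379 to 6800401, GRCm38) stood at 60.8 and 63 CPM in WT with DMSO and at 34.3 and 31.2 CPM in Rictor-KO. In GATA3-KO it stood at 36.2 and 32.3 CPM, so the knockout lines did not differ measurably in its mRNA (log2 fold change 0.06, adjusted p = 0.647). Against WT, Rictor fell by 0.92 on the log2 scale in Rictor-KO (SE 0.09, adjusted p = 3.31e-06) and fell by 0.86 in GATA3-KO (SE 0.09, adjusted p = 3.75e-06). With isorhamnetin it stood at 46 and 43.7 CPM in WT, 23 and 23.9 in Rictor-KO, and 28.5 and 27.6 in GATA3-KO. Rictor thus fell with the compound in WT (-0.46, SE 0.09, adjusted p = 0.00117), in Rictor-KO (-0.48, adjusted p = 0.0136) and in GATA3-KO (-0.29, adjusted p = 0.0347). The Rictor-KO call was lost without Rictor-KO DMSO replicate 1 (adjusted p = 0.0898), isorhamnetin replicate 1 (0.114) or isorhamnetin replicate 2 (0.0542). The GATA3-KO call was lost in 5 of 12 such runs, with a highest adjusted p of 0.355 without GATA3-KO DMSO replicate 1. Gata3 (ENSMUSG00000015619, chromosome 2, 9857078 to 9890034) was barely expressed, with 11 to 57 reads per library. Between the knockout lines under DMSO it did not differ past the threshold (GATA3-KO against Rictor-KO, log2 fold change -0.845, SE 0.582, adjusted p = 0.294). It was lower in GATA3-KO than in WT under DMSO (log2 fold change -2.25, SE 0.57, adjusted p = 0.00388). In Rictor-KO its log2 fold change was -1.40 (SE 0.54, adjusted p = 0.0507), which passed the threshold without Rictor-KO DMSO replicate 1 (adjusted p = 0.0403). A kept mRNA level does not contradict a knockout made by a small deletion.

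The first comparison asks what isorhamnetin changes in unedited cells. Inflammatory and interferon-induced transcripts fell, and antioxidant genes rose. Il1b, which encodes the pro-inflammatory cytokine interleukin-1 beta (ENSMUSG00000027398, chromosome 2, 129364570 to 129371139), stood at 2381 ± 364 CPM (SD, n = 2) in WT with DMSO and at 6.13 ± 5.5 CPM (SD, n = 2) with isorhamnetin. Its log2 fold change was -8.60 (SE 1.41, adjusted p = 0.00405). Il1a, which encodes the related cytokine interleukin-1 alpha (ENSMUSG00000027399, chromosome 2, 129299610 to 129309972), fell from 460 to 1.02 CPM (log2 fold change -8.80, SE 0.34, adjusted p = 3.71e-07). Nqo1, which encodes a quinone reductase (ENSMUSG00000003849, chromosome 8, 107388225 to 107403206), rose by 5.75 on the log2 scale (SE 0.51, adjusted p = 2.29e-06). Slc40a1, which encodes the iron exporter ferroportin (ENSMUSG00000025993, chromosome 1, 45908068 to 45926523), rose by 6.76 (SE 0.24, adjusted p = 1.08e-09).

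Of 37 tested inflammatory cytokines and NF-kB targets, 35 fell and 0 rose in WT, with 36 lower when adjusted over the list alone. Their median log2 fold change was -2.48 (camera adjusted p = 9.24e-34, adjusted p = 0.0637 with an estimated correlation). Csf3, which encodes the granulocyte growth factor G-CSF, fell from 229 ± 55.8 to 4.49 ± 1.75 CPM (SD, n = 2), and Cd80, a costimulatory ligand, fell by 2.49 on the log2 scale. Of 46 interferon-stimulated genes, 41 fell and 0 rose (42 lower adjusted over the list alone), with a median of -2.74 (adjusted p = 1.49e-51, and 0.0179 as adjusted p with an estimated correlation). Zbp1, a sensor of Z-form nucleic acids, had a log2 fold change of -3.71. The WT DMSO libraries stood apart from the knockout libraries in such genes: Il1b stood at 3.97 to 17.5 CPM on average in the 4 knockout groups. Csf3, Ccl22, Il27, Mmp9, Lif, Col5a3, P3h2 and Tnc, other genes with the largest falls, were chosen by the same rule. Members named below because at most 5 of a list moved one way were chosen after their values were seen. Tnc, which encodes the matrix protein tenascin-C, lost its call without WT DMSO replicate 1 (adjusted p = 0.0598) or replicate 2 (adjusted p = 0.064).

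Of 28 targets of NRF2, a transcription factor of the oxidative stress response, 27 rose in WT and 0 fell, also when adjusted over the list alone, by a median of 1.08 (adjusted p = 5.85e-32, adjusted p = 0.00308 with an estimated correlation). Gclm, a subunit of the enzyme that limits glutathione synthesis, rose from 97.5 ± 4.85 to 588 ± 43.3 CPM (SD, n = 2). Srxn1, which encodes sulfiredoxin, had a log2 fold change of 2.12 and Gsr, which encodes glutathione reductase, of 1.56. Of 11 genes of the metal response list, which shares 3 members with the NRF2 list, 6 rose and 4 fell, also when adjusted over the list alone (adjusted p = 0.0062, adjusted p = 0.318 with an estimated correlation). The metal genes that fell were Mt1, Mt2, Tfrc and Slc11a2. The ferritin gene Ftl1 rose by 0.95 and Hmox1, which encodes a heme oxygenase, by 1.3, while the metallothionein genes Mt1 and Mt2 fell by 0.40 and by 1.43. Cxcr4 and S1pr1, which encode receptors of migrating leukocytes, and Gpnmb, which encodes a membrane glycoprotein of macrophages, were among the genes with the largest increases.

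Genes of growth and the cell cycle also moved in WT. Of 55 genes of S phase and DNA replication, 49 rose (50 adjusted over the list alone) by a median of 0.54 (adjusted p = 3.34e-17, adjusted p = 0.103 with an estimated correlation), among them E2f2 at 1.35 and Tk1 at 1.49. Of 45 G2/M genes, 32 rose and 1, Ckap2l, fell (37 and 1 adjusted over the list alone, adjusted p = 2.48e-09, adjusted p = 0.318 with an estimated correlation). Of 49 genes of Myc and ribosome biogenesis, 35 fell (38 adjusted over the list alone, adjusted p = 9.42e-10, adjusted p = 0.199 with an estimated correlation), and Myc stood at 109 CPM with DMSO and 40.5 with isorhamnetin. Of 71 cytosolic ribosomal protein genes, 40 fell (52 adjusted over the list alone), by a median of -0.28 (adjusted p = 6.63e-06, adjusted p = 0.725 with an estimated correlation). Of 33 immediate early genes, 18 fell and 4 rose (19 and 4 adjusted over the list alone, adjusted p = 1.07e-07, adjusted p = 0.199 with an estimated correlation), with Dusp2, a phosphatase of MAP kinases, at -2.58, and Atf3, Klf2, Klf4 and Etv5 higher. Of 43 lysosomal genes and TFEB targets, 22 rose and 6 fell (24 and 7 adjusted over the list alone, adjusted p = 9.34e-06, adjusted p = 0.199 with an estimated correlation), with Lipa, the lysosomal acid lipase, at 2.75. In all, 2336 genes were higher and 2157 lower in WT with isorhamnetin, of which 1059 changed at least 2-fold. The count was 2785 without WT DMSO replicate 2 and 2567 without WT isorhamnetin replicate 2. The plots of CPM per library and of list medians show these genes and lists.

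**Figure D1:**
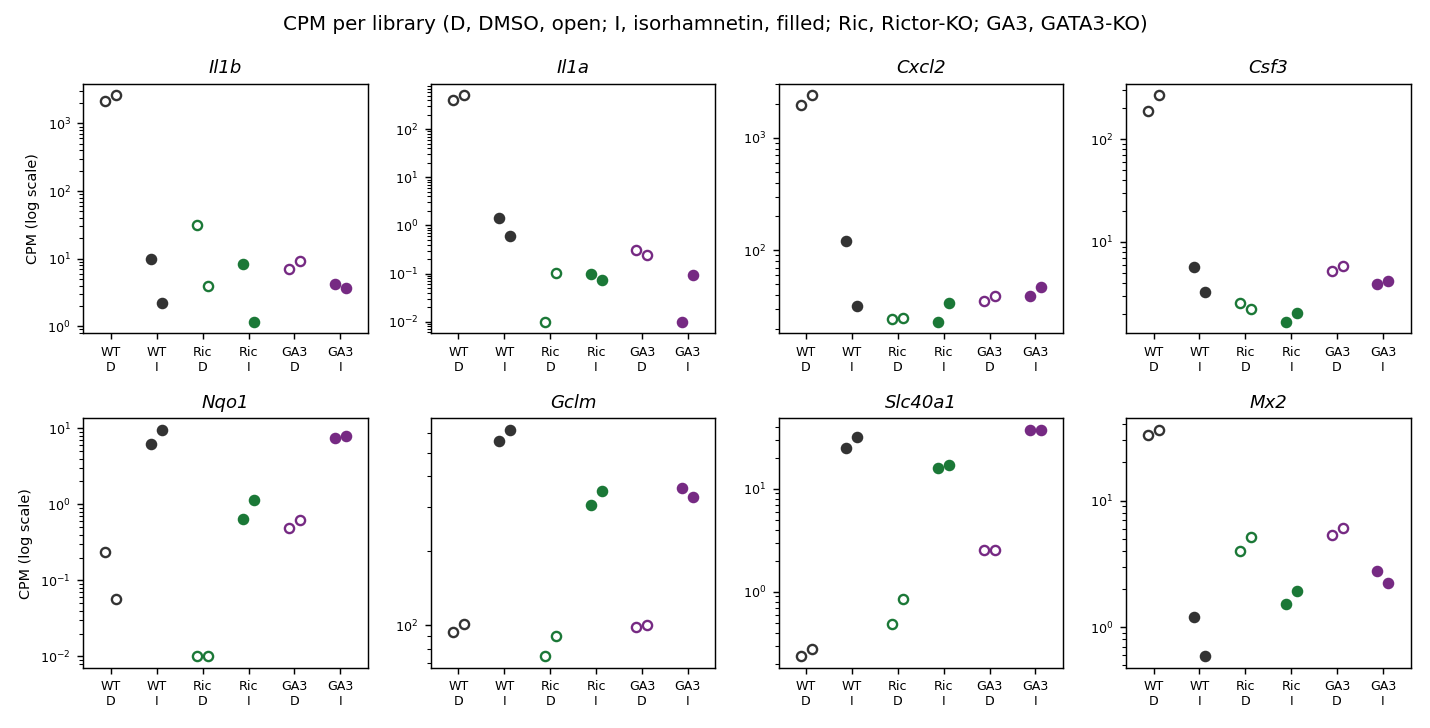
Expression in CPM, on a log axis, of Il1b, Il1a, Cxcl2, Csf3, Nqo1, Gclm, Slc40a1 and Mx2 in each of the 12 libraries, open for DMSO and filled for isorhamnetin; libraries with 0 CPM are drawn at 0.01. Il1b stands at 2381 CPM on average in WT with DMSO and Gclm rises with isorhamnetin in all 3 genotypes.

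**Figure D2:**
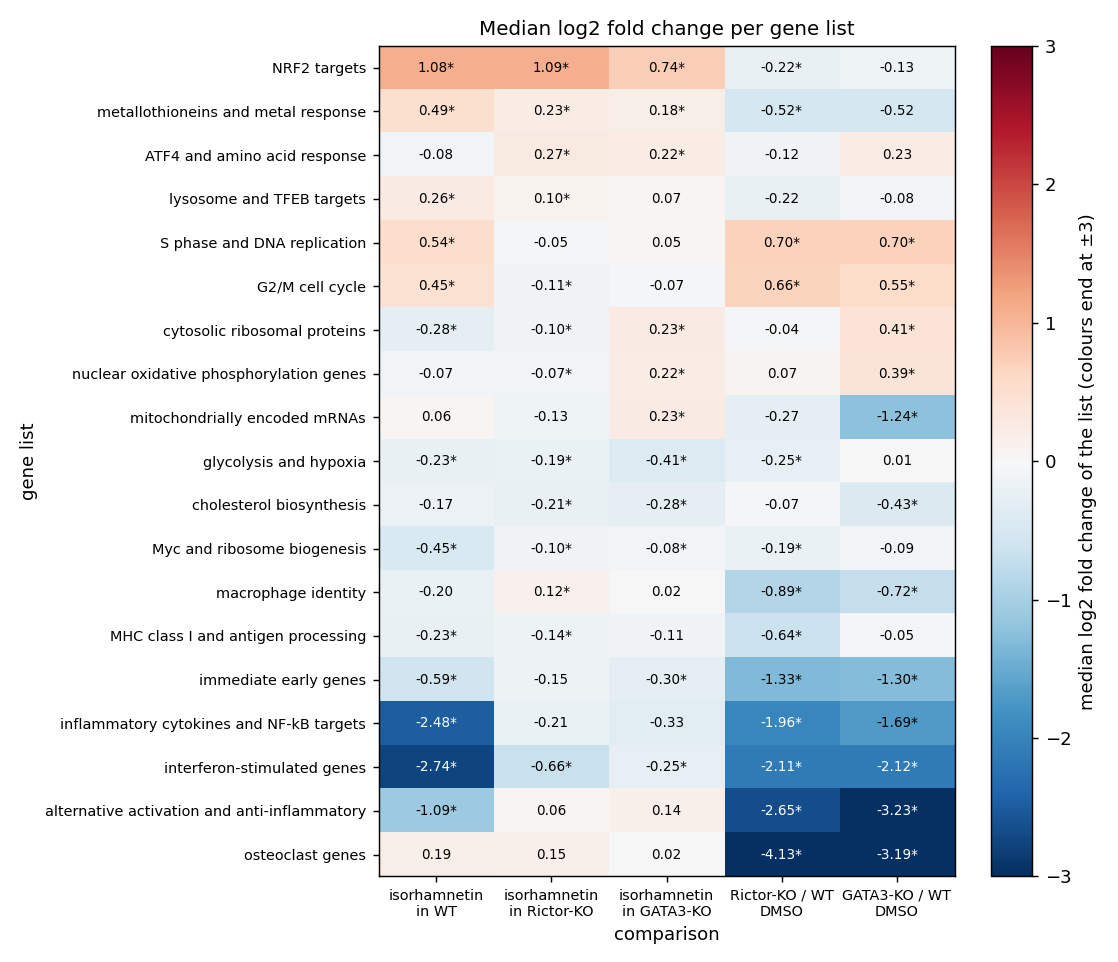
Median log2 fold change of 19 gene lists in 5 comparisons, as colours that end at 3 and -3, with a star where camera gave an adjusted p under 0.05 at the preset correlation. NRF2 targets have medians of 1.08 in WT, 1.09 in Rictor-KO and 0.74 in GATA3-KO with isorhamnetin.

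In Rictor-KO cells the question was which changes occur in a line labelled as lacking Rictor. NRF2 targets again rose. Of the 28 NRF2 targets, 18 rose (22 adjusted over the list alone) and 0 fell, by a median of 1.09 (adjusted p = 1.54e-111, adjusted p = 6.11e-05 with an estimated correlation). Gclm (ENSMUSG00000028124, chromosome 3, 122245557 to 122270732) rose from 82.7 to 328 CPM (log2 fold change 1.99, SE 0.11, adjusted p = 1.05e-07). Nqo1 had 0 reads with DMSO and 72 with isorhamnetin, at least 22.5-fold higher, and Trim16 had 2 and 84, which is 39.4-fold higher (95% counting interval 10.6 to 331). Slc7a11, the cystine transporter, rose from 35 to 284 CPM, and Slc40a1 rose by 4.61 on the log2 scale (SE 0.21, adjusted p = 2.76e-08). Of the 11 metal response genes, 4 rose: Slc40a1, Hmox1, Ftl1 and Fth1 (5 adjusted over the list alone, adjusted p = 1.09e-26, adjusted p = 0.00812 with an estimated correlation). Of 34 genes of ATF4 and the amino acid response, 5 rose (18 adjusted over the list alone, adjusted p = 5.67e-19, adjusted p = 0.0938 with an estimated correlation): Gpt2, Slc7a11, Trib3, Slc3a2 and Asns, of which the last had a log2 fold change of 0.42. Of 46 interferon-stimulated genes, 7 fell (17 adjusted over the list alone), with a median of -0.66, or -0.65 with genes of 0 reads at their bound (adjusted p = 4.37e-16, adjusted p = 0.164 with an estimated correlation). Of 37 inflammatory genes, Tnfaip2 rose by 1.53 and Icam1 and Cd80 fell by 0.37 and by 0.71 (2 higher and 3 lower adjusted over the list alone, list adjusted p = 0.0827). A replicate block within genotype, which takes equal replicate numbers as pairs, called 1420 genes (672 higher, 748 lower). Without it, 169 genes were higher and 57 lower in all, 59 of them at least 2-fold. The count and the balance of directions thus depend on that choice. DESeq2 called 424 genes and the fit of these 4 libraries alone 36, and the count was 143 without Rictor-KO isorhamnetin replicate 1 and 147 without Rictor-KO DMSO replicate 2. Of 20 genes the naming rule chose here, 9 lost their call when a library was left out, with a highest adjusted p of 0.266, for Oas3 and Xaf1 without Rictor-KO isorhamnetin replicate 1. In the fit of these 4 libraries alone 14 of the 20 lost it, among them Nqo1 (adjusted p = 0.141), while Gclm, Slc40a1 and Slc7a11 kept it. Oas3 is an antiviral enzyme gene.

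In GATA3-KO cells the same question was asked of the other line. NRF2 targets rose here as well: 22 of 28 rose (23 adjusted over the list alone), by a median of 0.74 (adjusted p = 8.71e-37, adjusted p = 0.00216 with an estimated correlation). Gclm rose from 98.9 to 344 CPM with a log2 fold change of 1.8, Nqo1 by 3.78 and Slc40a1 by 3.87 (SE 0.18, adjusted p = 3.55e-08). Of 35 glycolysis and hypoxia genes, 24 fell and 1, Hk3, rose (24 and 2 adjusted over the list alone, adjusted p = 2.07e-09, adjusted p = 0.123 with an estimated correlation), with the glycolytic enzyme genes Pfkl at -0.86 and Hk2 at -1.15. Of 71 cytosolic ribosomal protein genes, 25 rose (31 adjusted over the list alone) by a median of 0.24 (adjusted p = 1.36e-07, adjusted p = 0.824 with an estimated correlation). Of 75 nuclear oxidative phosphorylation genes, 24 rose and 1, Sdha, fell (29 and 1 adjusted over the list alone, adjusted p = 2.98e-07, adjusted p = 0.811 with an estimated correlation). Of 24 cholesterol biosynthesis genes, 9 fell (10 adjusted over the list alone, adjusted p = 8.5e-05, adjusted p = 0.773 with an estimated correlation), with Srebf2, the transcription factor of the pathway, at -0.73. Of 20 fatty acid synthesis genes, 9 fell, also when adjusted over the list alone (adjusted p = 0.00187, adjusted p = 0.62 with an estimated correlation), with the desaturase gene Scd2 at -0.86. Of 35 mTOR and Akt pathway genes, 14 fell and 3 rose: Mlst8, Rheb and Eif4ebp1 (16 and 3 adjusted over the list alone, adjusted p = 0.00456, adjusted p = 0.675 with an estimated correlation). Of 46 interferon-stimulated genes, 11 fell and 1, Oas1g, rose, also when adjusted over the list alone, with a median of -0.25 (adjusted p = 0.0126, adjusted p = 0.824 with an estimated correlation). With the replicate block within genotype 5176 genes were called (2349 higher, 2827 lower). Without it, 1209 genes were higher and 1883 lower in all, 126 at least 2-fold. The count fell to 544 without GATA3-KO isorhamnetin replicate 2 and to 549 without GATA3-KO DMSO replicate 1. Of the 20 genes chosen by the naming rule, 12 lost their call in such a run, with a highest adjusted p of 0.296 for Slc8a1 without GATA3-KO DMSO replicate 1, and 5 lost it in the fit of the 4 compared libraries alone.

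Averaged over the genotypes, isorhamnetin raised 2033 genes and lowered 2259, 345 of them at least 2-fold. NRF2 targets rose in 26 of 28 cases (27 adjusted over the list alone), by a median of 0.92 (adjusted p = 2.1e-75, adjusted p = 0.000239 with an estimated correlation). Of 46 interferon-stimulated genes, 36 fell and 0 rose (37 lower adjusted over the list alone), with a median of -1.28 (adjusted p = 7.59e-37, adjusted p = 0.0441 with an estimated correlation). Of 37 inflammatory genes 27 fell and 1, Tnfaip2, rose (29 and 1 adjusted over the list alone, adjusted p = 2.93e-16, adjusted p = 0.189 with an estimated correlation). Slc40a1 rose by 5.08 on the log2 scale (SE 0.12, adjusted p = 4.24e-12) and Mx2, an interferon-induced GTPase gene annotated as a polymorphic pseudogene, fell by 2.62. In the knockout lines alone, a setting chosen after seeing the data, 1646 genes were called (632 higher, 1014 lower). There, 23 of 28 NRF2 targets rose with a median of 0.85, 20 of 43 interferon-stimulated genes fell with a median of -0.42, and of 34 inflammatory genes 7 fell and 2, Ccl2 and Tnfaip2, rose, with a median of -0.25 (adjusted p = 0.0129, 0.00668 as the fry p). Il1b, with a mean log2 fold change of -3.83, was not past the threshold in the knockouts alone (adjusted p = 0.373). Nor were Il27 (adjusted p = 0.198), Ccl22 (0.45), Csf3 (0.15), P3h2 (0.0931) and Lcn2 (0.102).

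Across 11808 genes, which are not independent replicates, the log2 fold changes of WT correlated with those of Rictor-KO at Pearson r = 0.249 (Spearman 0.393) and with those of GATA3-KO at 0.198 (Spearman 0.224). The knockout lines correlated with each other at 0.166 (Spearman 0.273). Over the 7846 genes of mean log2 CPM of at least 4, the Pearson values were higher, at 0.501, 0.302 and 0.429 in the same order. These pairs of effects share no libraries. Of 226 genes called in Rictor-KO, 210 (92.9%) had the same sign in WT, and of 3092 called in GATA3-KO, 2038 (65.9%) did. Of 196 genes called in both WT and Rictor-KO, 187 had the same sign. Of these, 138 were higher in both and 49 lower in both, where independent lists give 33.4 and 10.4. For WT and GATA3-KO, 1412 genes were called in both, and only 1070 of them had the same sign. There, 410 were higher in both and 660 lower in both, where independent lists give 239.2 and 344, and the rest went opposite ways. In all 3 genotypes 90 genes rose and 41 fell. Slc40a1, Gclm, Srxn1, Hmox1, Ftl1, Cat, Slc7a11 and Gsr rose in each, and Stat3, Icam1 and Cd80 fell in each. The scatter plot sets these effects side by side.

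**Figure D3:**
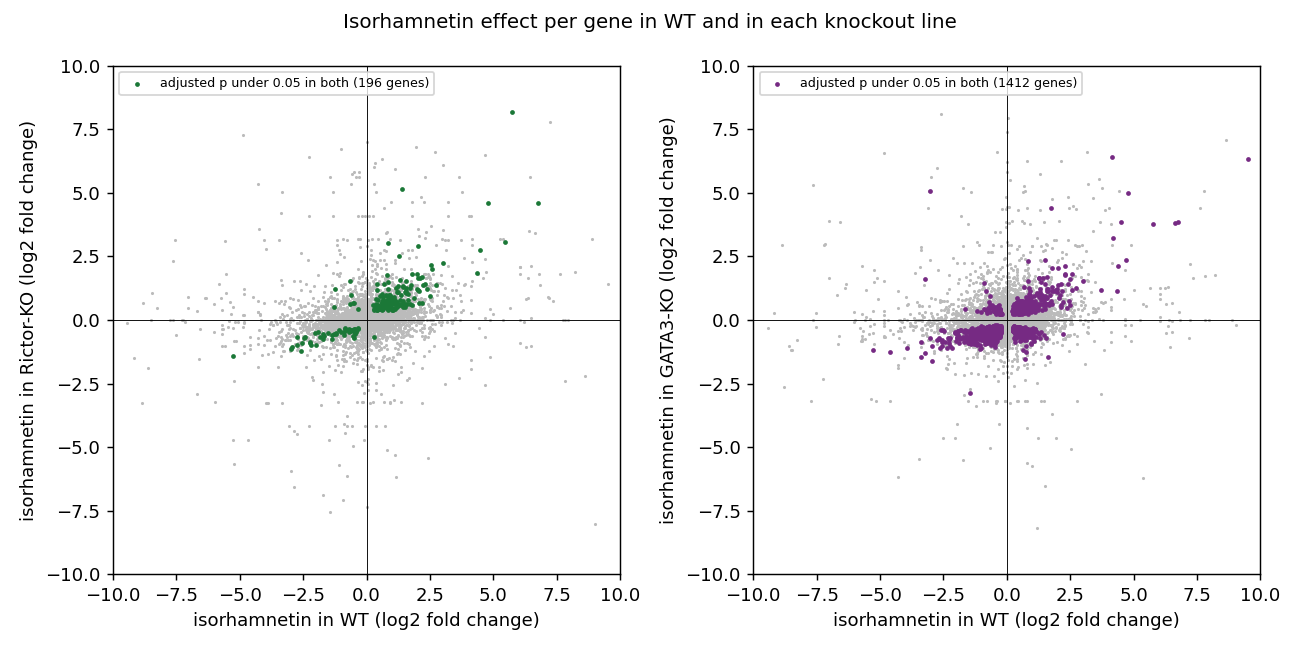
Log2 fold change with isorhamnetin in WT, on the horizontal axis, against that in Rictor-KO and in GATA3-KO, 1 point per gene, with genes called in both genotypes marked and axes ending at 10 and -10. Genes called in both number 196 for WT and Rictor-KO, 187 of them with the same sign. For WT and GATA3-KO they number 1412, of which 1070 have the same sign.

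The next comparison asked whether the response differed between genotypes, as a test of the difference itself. The response of Rictor-KO was above that of WT for 785 genes and below it for 839, and that of GATA3-KO above for 1470 and below for 1833. Inflammatory genes fell more in WT: 27 of 37 had a higher response in Rictor-KO (32 adjusted over the list alone), with a median difference of 2.0 (adjusted p = 2.64e-37, adjusted p = 0.076 with an estimated correlation). In GATA3-KO it was 25 of 37 (29 adjusted over the list alone), with a median of 2.39 (adjusted p = 8.1e-26, adjusted p = 0.168 with an estimated correlation). Of 46 interferon-stimulated genes, 36 differed the same way in Rictor-KO (37 adjusted over the list alone, adjusted p = 4.5e-43, adjusted p = 0.076 with an estimated correlation) and 40 in GATA3-KO (41 adjusted over the list alone, adjusted p = 1.55e-41, adjusted p = 0.103 with an estimated correlation). The response of S phase genes was below that of WT for 43 of 55 in Rictor-KO (49 adjusted over the list alone, adjusted p = 1.72e-26, adjusted p = 0.076 with an estimated correlation) and for 38 in GATA3-KO (39 adjusted over the list alone, adjusted p = 7.7e-16, adjusted p = 0.168 with an estimated correlation). NRF2 targets responded less in GATA3-KO for 12 of 28 and more for 1, Slc7a11 (12 and 2 adjusted over the list alone, adjusted p = 0.00334, adjusted p = 0.282 with an estimated correlation). In Rictor-KO 8 responded less and 3, Slc7a11, Txnrd1 and Sqstm1, more (9 and 3 adjusted over the list alone), and the list was not called (adjusted p = 0.0658). These differences contrast with WT DMSO libraries in which Il1b stood at 2381 CPM. Rictor and Gata3 did not differ in response past the threshold. The Rictor-KO count was 779 without WT DMSO replicate 2 and 804 without WT isorhamnetin replicate 2. The GATA3-KO count was 1799 without GATA3-KO isorhamnetin replicate 2, 1842 without WT isorhamnetin replicate 2, 1858 without WT DMSO replicate 2 and 1998 without GATA3-KO DMSO replicate 1.

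Under DMSO, Rictor-KO was compared with WT to find the changes that come with the line. Inflammatory, interferon and macrophage genes were lower and proliferation genes higher. Of 37 inflammatory genes 33 were lower and 1, Nos2, which encodes the inducible nitric oxide synthase, was higher, with a median of -1.96 (34 and 1 adjusted over the list alone, adjusted p = 1.25e-23, adjusted p = 0.0875 with an estimated correlation). Of 46 interferon-stimulated genes, 43 were lower (45 adjusted over the list alone), by a median of -2.11 (adjusted p = 7.44e-27, adjusted p = 0.0875 with an estimated correlation), with Ifi44 at -5.46. Of 35 genes of macrophage identity 23 were lower and 2, Fcgr4 and Trem2, higher (25 and 3 adjusted over the list alone). The median was -0.89, and the lipopolysaccharide coreceptor gene Cd14 had -3.02 (adjusted p = 1.24e-08, adjusted p = 0.0875 with an estimated correlation). Of 20 alternative activation genes, 16 were lower, also when adjusted over the list alone, with a median of -2.66 (adjusted p = 7.12e-09, adjusted p = 0.0875 with an estimated correlation), and of 11 osteoclast genes, 8 were lower, also when adjusted over the list alone (adjusted p = 1.37e-08, adjusted p = 0.0743 with an estimated correlation), among them Ctsk at -5.61. Of 55 S phase genes 54 were higher (55 adjusted over the list alone), by a median of 0.70 (adjusted p = 1.57e-25, adjusted p = 0.0743 with an estimated correlation), and of 45 G2/M genes 44 were higher by 0.66, also when adjusted over the list alone (adjusted p = 4.24e-22, adjusted p = 0.0875 with an estimated correlation). Tfec, a transcription factor gene of the Mitf family (ENSMUSG00000029553, chromosome 6, 16833373 to 16898441), had 12.9 CPM in WT with DMSO and was at least 327-fold lower in Rictor-KO. The Y-linked genes Ddx3y (ENSMUSG00000069045, chromosome Y, 1260771 to 1286629), Eif2s3y and Uty were at least 1570-fold, 1030-fold and 389-fold lower. Cfap69, with 0 reads in WT and 587 in Rictor-KO, was at least 179-fold higher. In all, 2283 genes were higher and 2446 lower, 1336 at least 2-fold.

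GATA3-KO was compared with WT in the same way. Interferon-stimulated genes were lower in 44 of 46 cases (45 adjusted over the list alone), by a median of -2.12 (adjusted p = 6.85e-17, adjusted p = 0.2 with an estimated correlation), and inflammatory genes in 31 of 37, also when adjusted over the list alone, with Nos2 higher (median -1.69, adjusted p = 1.47e-15, adjusted p = 0.245 with an estimated correlation). Of 55 S phase genes 50 were higher (51 adjusted over the list alone), by 0.70 (adjusted p = 7.47e-17, adjusted p = 0.18 with an estimated correlation). Of 13 mitochondrially encoded transcripts, 12 were lower, also when adjusted over the list alone, with a median of -1.24 (adjusted p = 6.05e-10, adjusted p = 0.254 with an estimated correlation), and mt-Co3, a cytochrome c oxidase subunit, had -1.71. These transcripts took 0.46% and 0.47% of exon reads in the GATA3-KO libraries under DMSO. In contrast, 53 of 75 nuclear oxidative phosphorylation genes and 57 of 71 ribosomal protein genes were higher (57 and 61 adjusted over the list alone, adjusted p = 1.93e-07 and 2.83e-07, adjusted p = 0.562 and adjusted p = 0.633 with an estimated correlation). Tfec was at least 345-fold lower, Tnc at least 1250-fold, Il13ra2, a decoy receptor of interleukin-13, at least 536-fold, and Ccr1, a chemokine receptor, at least 469-fold. Gda and St6gal1 lost their calls in some runs without a library, with highest adjusted p of 0.0731 without WT DMSO replicate 2 and 0.0592 without WT DMSO replicate 1. In all, 3167 genes were higher and 3196 lower, 1824 at least 2-fold. Outside chromosome 17, a setting chosen after seeing the data, 5939 genes were called.

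The knockout effects went the same way at many genes. Of genes called in both lines, 1717 were higher in both, 1877 lower in both and 114 opposite, where independent lists give 612.3 and 662. The covariance of the log2 fold changes was 1.40 (r = 0.684). Unchanged groups simulated against the same WT libraries gave a covariance of 0.107 and r of 0.514, and separate WT DMSO libraries for the lines gave covariances of 1.34 and 1.29. Part of the agreement may thus come from the shared libraries. Under isorhamnetin, 1147 of the 3594 genes shared under DMSO (31.9%) were again called the same way in both lines, where lists independent within these genes give 24.5%. With separate WT isorhamnetin libraries, also chosen after seeing the data, it was 22.1% and 20.7%, where independent lists give 16.4% and 15.1%. Simulated unchanged groups gave 0%, but they called only 0.2 of these genes per line on average, so that value is no comparison. The effect of isorhamnetin in WT also correlated with the knockout effects: covariance 0.498 for Rictor-KO and 0.451 for GATA3-KO, against simulated values of 0.109 and 0.108. With separate WT DMSO libraries, a setting chosen after seeing the data, they were 0.418 and 0.408 for Rictor-KO and 0.395 and 0.343 for GATA3-KO. Of 220 genes at least 4-fold lower with isorhamnetin in WT, 170 were lower and 9 higher in Rictor-KO, and 161 and 17 in GATA3-KO. Of 158 genes at least 4-fold higher, 44 were higher and 29 lower in Rictor-KO, and 50 and 38 in GATA3-KO. These counts share the WT DMSO libraries, and the higher genes divided far more evenly than the lower ones.

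The knockout lines were compared directly to find where they part. Y-linked genes were far higher in GATA3-KO: Eif2s3y at least 1980-fold, Ddx3y at least 1930-fold and Uty at least 647-fold. Of 71 ribosomal protein genes 61 were higher, by a median of 0.45, and 11 of 13 mitochondrially encoded transcripts were lower, by a median of -0.82 (64 and 11 adjusted over the list alone, adjusted p = 2.47e-16 and 1.23e-12, adjusted p = 0.894 and adjusted p = 0.839 with an estimated correlation). Of 22 genes of MHC class I and antigen processing, 16 were higher, also when adjusted over the list alone (adjusted p = 3.36e-11, adjusted p = 0.4 with an estimated correlation). Of these genes, 13 lie on chromosome 17, and all 13 were higher. Mki67, a proliferation marker, had a log2 fold change of -1.07. Genes on chromosome 17 stood higher in GATA3-KO than in WT as a whole, with a median log2 fold change of 0.54 under DMSO and 0.53 under isorhamnetin over 631 genes, where shuffled positions gave -0.077 to 0.098. Of the chromosome 17 genes 373 were higher and 51 lower in GATA3-KO than in WT under DMSO. The 13 genes of MHC class I and antigen processing there went the other way, with a median of -0.22 against WT and 6 lower. In all, 1822 genes were higher and 1737 lower in GATA3-KO than in Rictor-KO, 654 at least 2-fold. The count was 1688 without GATA3-KO DMSO replicate 2 and 3183 outside chromosome 17. Lyz1 (adjusted p = 0.155), Magohb (0.12), Ms4a6b (0.0892) and Gcat_2 (0.129) lost their calls without that library, as did Lyz1 (0.168) and Ms4a6b (0.0973) in the fit of the compared libraries alone. Gcat_2 had 0.1% unique reads and is uncertain.

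**Figure D4:**
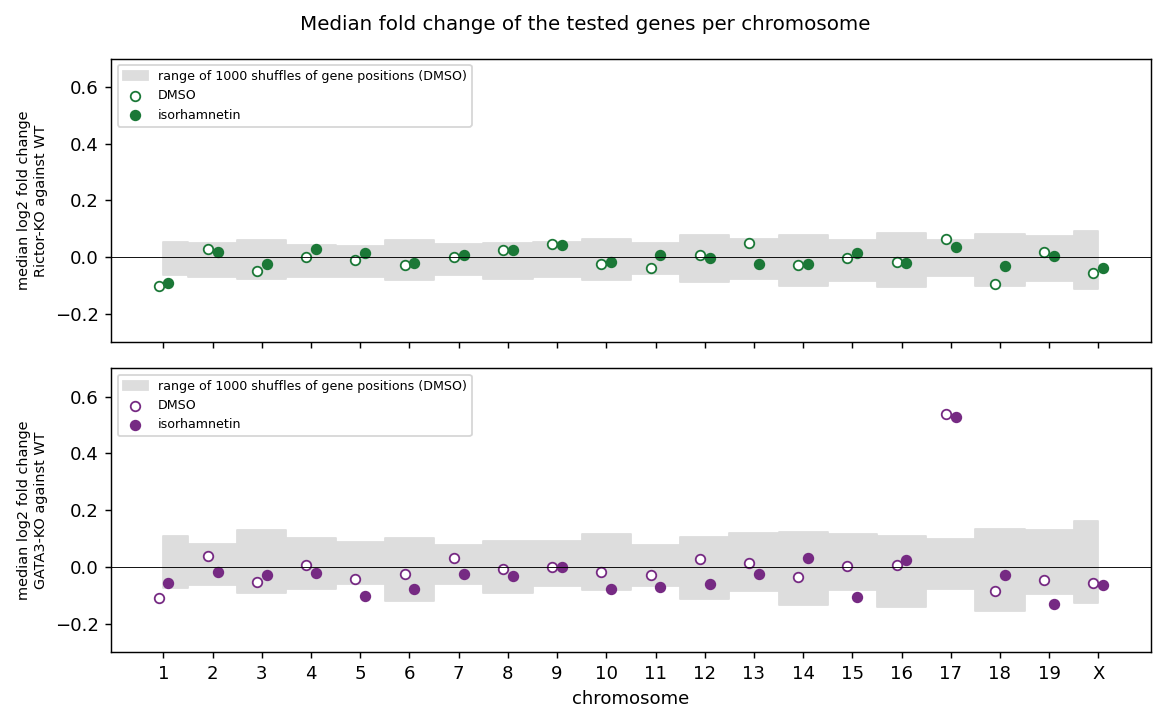
Median log2 fold change of the tested genes of each chromosome in each knockout line against WT, under DMSO and isorhamnetin, with the range of 1000 shuffles of gene positions in grey. Chromosome 17 stands at 0.54 in GATA3-KO under DMSO.

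The authors' deposited tables compare isorhamnetin with DMSO in each genotype over 25683 genes. They list 5241 genes with a false discovery rate under 0.05 in WT (2717 higher, 2524 lower), 156 in Rictor-KO (118 higher, 38 lower) and 2855 in GATA3-KO (1267 higher, 1588 lower). The deposited fold changes correlated with those fitted here at a Spearman rho of 0.9999 in WT, 0.9998 in Rictor-KO and 0.9998 in GATA3-KO, across genes that are not independent replicates. Of genes called by both, 4323, 121 and 2457, 0 had opposite signs.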

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

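The tests of scaling, exchanged libraries, neutrophils, the interferon part, shared WT libraries, covariance and share kept under isorhamnetin with separate WT libraries, line history and the Y-linked genes were chosen only after the results were seen.

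The response to isorhamnetin differed from that of WT, by a test of the difference itself, for 1624 genes in Rictor-KO and 3303 in GATA3-KO. The largest differences above WT in Rictor-KO were those of Il1a (9.49), Ccl2 (6.75), Shox2 (6.36), Mmp9 (6.07), Ccl22 (5.36), Csf3 (5.31), Itgax (5.24), P3h2 (5.18), Cxcl2 (5.05) and Zfp811 (5.03), on the log2 scale. Those below WT were Map2k6 (-2.96), Gpnmb (-2.82), Adh7 (-2.71), Fblim1 (-2.56), Ndrg4 (-2.53), Fam131a (-2.52), Kitl (-2.52), Aph1c (-2.46), Arhgap24 (-2.28) and Fndc10 (-2.28). Of these 20, 8 lost their call when a library was left out. The highest adjusted p was 0.296 for Fblim1 and 0.201 for Gpnmb without Rictor-KO DMSO replicate 1; both also lost it in the fit of the compared libraries alone (0.101 and 0.0907). It was 0.13 for Il1a, 0.119 for Itgax and 0.0927 for Shox2 without Rictor-KO isorhamnetin replicate 1, 0.128 for Kitl and 0.06 for Fam131a without WT DMSO replicate 2, and 0.0555 for Arhgap24 without WT isorhamnetin replicate 2. In GATA3-KO the differences above WT were those of Col5a3 (10.16), Ccr1 (8.09), Il1b (7.57), Mmp9 (5.40), Csf3 (5.22), Zfp811 (5.22), Cxcl2 (5.05), P3h2 (4.89), Ccl22 (4.88) and Slc5a1 (4.86). Those below WT were Ndrg4 (-3.22), C77080 (-3.16), Slc8a1 (-3.08), Map2k6 (-2.99), Fndc10 (-2.96), Fblim1 (-2.96), Nanos1 (-2.94), Slc40a1 (-2.89), Plxnd1 (-2.73) and Myh7b (-2.65). Here 4 lost their call when a library was left out: Col5a3 (highest adjusted p 0.124 without GATA3-KO isorhamnetin replicate 1), Slc5a1 (0.106 without WT DMSO replicate 1), Il1b (0.0924 without GATA3-KO DMSO replicate 1) and Fblim1 (0.0644 without GATA3-KO isorhamnetin replicate 2). Ccr1, Shox2 and Slc5a1 had 0 reads in a group, Itgax and P3h2 1, Col5a3 2 and Il1a 4, so their fitted differences depend on the prior count and are no bounds. Between 2 groups, Itgax had 1 read with DMSO and 8 with isorhamnetin in Rictor-KO, a ratio of 7.51 (95% counting interval 1.01 to 333). P3h2 fell 54.4-fold in WT (9.31 to 2190). Ccr1 was at least 2.74-fold higher with isorhamnetin in GATA3-KO, a call lost in most runs without a library.

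Whole lists differed in response too, at the preset correlation; none of these calls held with an estimated correlation. The median difference in Rictor-KO was 2.0 for the inflammatory list, 1.81 for interferon-stimulated genes, 0.94 for alternative activation, 0.60 for immediate early genes, 0.46 for macrophage identity, 0.37 for ATF4, 0.36 for adhesion and 0.31 for Myc and ribosome biogenesis. It was -0.59 for S phase, -0.55 for G2/M, -0.35 for fatty acid synthesis and -0.22 for lysosomal genes. In GATA3-KO it was 2.39 for the inflammatory list, 2.14 for interferon-stimulated genes, 0.73 for alternative activation, 0.71 for adhesion, 0.52 for ribosomal proteins, 0.41 for immediate early genes and 0.34 for Myc and ribosome biogenesis. It was -0.57 for S phase, -0.56 for G2/M, -0.52 for fatty acid synthesis, -0.47 for NRF2 targets and -0.18 for lysosomal genes. Intron reads, which no comparison above uses, gave 1686 called genes for isorhamnetin in WT.

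Inflammatory and interferon transcripts were high in WT with DMSO, where Il1b stood at 2381 CPM. With median-of-ratios size factors the inflammatory list still had a median of -2.5 in WT, so the choice between these 2 scalings is not the cause. Those factors lay close to the TMM ones, at 0.904 and 0.905 against 0.912 and 0.913 for the WT DMSO libraries. A scaling error common to both methods was therefore not tested. An exchange of libraries between treatments would put Gclm out of place, but its lowest isorhamnetin library stood at least 3.31 times above its highest DMSO library in each genotype, and neutrophils among the cells would bring S100a8 and S100a9, which summed to 0.172 CPM in WT with DMSO. In the knockout lines alone the interferon list still had a median of -0.415 and the inflammatory list of -0.253. A state of the WT DMSO cultures outside the labels cannot cause those smaller falls. They do not decide how much, or whether all, of the far larger fall in WT comes from such a state. The design has 1 set of WT DMSO libraries, so no biological explanation was tested.

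Both knockout lines differed from WT the same way at many genes. The WT libraries they share cannot be the whole cause, since separate WT DMSO libraries still gave a covariance of 1.294, against 0.107 in simulations. Under isorhamnetin, with separate WT isorhamnetin libraries, the covariance was still at least 1.124, against 0.103 in simulations. A state confined to the WT DMSO libraries thus cannot be the whole cause of such agreement. A state that WT cultures of both treatments share was not tested, since it would enter here too and separate libraries may come from the same culture. The share of genes kept under isorhamnetin decides nothing on either state. With separate libraries it was as low as 20.7%, where lists independent within these genes give 15.1%. A line history that the knockouts share and the WT cells do not cannot be told apart from common effects of the knockouts. Only 1 gene, Tfec, had at least 5 CPM in each WT library and at most 3 reads in each knockout library. Independent lists of the 9 and 7 such genes per line give 0.00534. Tmem26 (at most 4 reads in a knockout group), Mcoln2 (at most 6) and Stc2 (at most 9) came close. In the other direction there were 0, while Cfap69 had at most 2 reads in a WT group and at least 330 in a knockout group.

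Y-linked transcripts were near 0 in the Rictor-KO libraries, with at most 1 read of a tested Y-linked gene in a library. Loss or silencing of the whole chromosome predicts this, but the prediction restates the pattern and could not fail. All 4 tested genes lie between 897788 and 1286629 on chromosome Y, so they do not speak for the rest of the chromosome. Reads counted on the X-linked copies would raise those copies, but they summed to 1330 CPM in Rictor-KO and 1768 CPM in WT under DMSO. The Y-linked genes summed to 139.3 CPM in WT. In GATA3-KO, which kept its Y-linked reads, the copies were also lower than in WT under DMSO. Their log2 fold changes there ran from -0.291 for Eif2s3x to -0.943 for Ddx3x. A rise of 139.3 CPM could thus be hidden in a larger fall, so the sum does not exclude such reads. A WT population mixed from cells with and without the chromosome may also fit, since all 4 Y-linked genes were higher in GATA3-KO than in WT under both treatments, but that cannot be told apart from a gain in GATA3-KO.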

How the results depend on the processing

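The knockout lines alone, the crossed WT numbers, the separate WT DMSO libraries for the isorhamnetin effect and the genes outside chromosome 17 are tests chosen only after the results were seen. Where a library was left out, the lone library of its group was assumed to vary like the other groups. Of 659 results for named genes, 611 were past the threshold, 507 never lost their call under any alternative run and 0 reversed; 293 of 7332 leave-one-out results lost it. Of 124 list calls, 8 held with an estimated correlation, 22 were lost with fry, and 124 held with median-of-ratios factors and with the replicate block. With an absolute log2 fold change of at least 1, the counts were 1059 for isorhamnetin in WT, 59 in Rictor-KO (52 higher, 7 lower), 126 in GATA3-KO (90 higher, 36 lower), 345 averaged, 530 and 806 for the differences in response of Rictor-KO and GATA3-KO, 1336 and 1824 for these lines against WT, and 654 between them. For isorhamnetin in Rictor-KO, DESeq2 called 424 genes and the compared libraries alone 36, and averaged over genotypes the knockout lines alone gave 1646; the cause was not tested.

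The replicate block over all 12 libraries gave 4672 genes for isorhamnetin in WT and changed no count by more than 1.5 times. The replicate block within genotype gave 1420 genes (672 higher, 748 lower) for isorhamnetin in Rictor-KO, 5176 in GATA3-KO, and 3601 and 5320 for the differences in response. Same-numbered libraries deviated together in Rictor-KO (r = 0.45 across genes, 0.80 for highly expressed genes) and at high expression in GATA3-KO (0.07 and 0.69). In WT they did not (-0.03 and -0.18), and the numbers were not taken as pairs in the main model. The WT values do not decide this for the knockout lines, whose counts and balance of higher and lower genes depend on that choice. With crossed numbers 6388 genes were called in WT, against 6208.

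Leaving out each library in turn gave 2567 to 4631 genes for isorhamnetin in WT, 143 to 249 in Rictor-KO, 544 to 3388 in GATA3-KO and 3431 to 4236 averaged. It gave 779 to 1671 and 1799 to 3523 for the differences in response, 3177 to 4844 for Rictor-KO and 4986 to 6519 for GATA3-KO against WT, and 1688 to 3644 between them. The lowest counts came without WT isorhamnetin replicate 2, Rictor-KO isorhamnetin replicate 1 and GATA3-KO isorhamnetin replicate 2 for the 3 genotypes. For genes of mean log2 CPM of at least 4, correlations across genes were 0.501, 0.302 and 0.429 between the isorhamnetin effects, 0.738 between the knockout effects, and 0.524 and 0.431 between isorhamnetin in WT and these. Separate WT DMSO libraries gave 0.587 and 0.557 for the knockouts, 0.255 and 0.244 for isorhamnetin with Rictor-KO, and 0.227 and 0.189 with GATA3-KO. Leaving out libraries gave 0.135 to 0.226, 0.122 to 0.19 and 0.078 to 0.153 for the isorhamnetin effects. The limma test on TPM was not run, since the files hold counts. Depth limits genes under about 3 reads per group.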

Other observations

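The tests of runs of genes along chromosome 17 and of the Rictor-KO replicates were chosen only after the result was seen. Other gene groups moved with isorhamnetin in WT. Of 35 glycolysis and hypoxia genes 14 fell and 4 rose: Hk1, Hk3, Pfkm and Bnip3l. Hk2, a hexokinase, stood at -1.05 and Hk3 at 1.14 (15 and 4 adjusted over the list alone, camera adjusted p = 0.00765, adjusted p = 0.353 with an estimated correlation). Of 22 genes of MHC class I and antigen processing 11 fell, among them the peptide transporter gene Tap1 at -1.37 (12 adjusted over the list alone, adjusted p = 0.000833, adjusted p = 0.318 with an estimated correlation). Of 27 adhesion and protease genes 12 fell and 5 rose, namely Cxcr4, Itga4, Cx3cr1, Mmp19 and Plau, with the integrin genes Itgal at -1.90 and Itgax at -2.60 (12 and 6 adjusted over the list alone, adjusted p = 0.00438, adjusted p = 0.199 with an estimated correlation). Of 20 alternative activation genes 8 fell and 3 rose: Klf4, Clec10a and Tgm2, also when adjusted over the list alone (adjusted p = 0.0104, adjusted p = 0.367 with an estimated correlation). Lists that camera did not call in WT include fatty acid synthesis, with 11 members higher and 2, Elovl1 and Acly, lower (adjusted p = 0.0637), heat shock, with 1, Hspa4l, higher and 11 lower (adjusted p = 0.0922), FoxO targets, with 11 and 7 (adjusted p = 0.978), and mTOR and Akt components, with 6 and 7 (adjusted p = 0.975). Of 10 genes of GATA factors and GATA3 targets Zfpm1 and Id2 were higher and Il1rl1 lower (adjusted p = 0.815).

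In the knockout lines isorhamnetin moved further lists. In Rictor-KO 5 of 35 glycolysis and hypoxia genes fell and 1 rose (13 and 1 adjusted over the list alone, adjusted p = 4.34e-06, adjusted p = 0.164 with an estimated correlation). The fallen genes were Bnip3, P4ha1, Pgam1, Pfkl and Ankrd37, named after their values were seen, and Hk3 rose. Of these, Ankrd37, Pgam1 and P4ha1 lost their calls when a library was left out, with adjusted p of 0.213 without Rictor-KO isorhamnetin replicate 2, and 0.176 and 0.0563 without Rictor-KO isorhamnetin replicate 1. For cholesterol biosynthesis the edgeR test called 0 of 24 genes, with 10 lower at an unadjusted p under 0.05 (list adjusted p = 1.33e-05, adjusted p = 0.626 with an estimated correlation). In GATA3-KO 14 of 34 genes of ATF4 and the amino acid response rose and 3 fell: Slc7a5, Slc38a2 and Nupr1 (15 and 4 adjusted over the list alone, adjusted p = 0.00187, adjusted p = 0.773 with an estimated correlation).

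Under DMSO both lines had lower adhesion and immediate early genes than WT. Of 27 adhesion genes 18 were lower in Rictor-KO and 16 in GATA3-KO (adjusted p = 1.24e-08 and 7.8e-07, adjusted p = 0.0743 and adjusted p = 0.18 with an estimated correlation). Of 33 immediate early genes 22 were lower and 4, Klf2, Zfp36l1, Spry2 and Etv5, higher in each line (adjusted p = 5.65e-10 and 5.34e-06, adjusted p = 0.101 and adjusted p = 0.254 with an estimated correlation). Of 10 genes of GATA factors and GATA3 targets, 3 were lower in Rictor-KO: Il1rl1, Cd200r1 and Hpgds (adjusted p = 0.0176, adjusted p = 0.185 with an estimated correlation). Id2 was higher. Hpgds lost its call without Rictor-KO DMSO replicate 2 (adjusted p = 0.0805) and Id2 without WT DMSO replicate 2 (adjusted p = 0.144). In GATA3-KO Il1rl1, Gata3, Hpgds and Cd200r1 were lower and Id2 higher (adjusted p = 0.0577).

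Markers of other cell types were mostly low. Neutrophil markers had 1 tested member, Csf3r, at 2.27 CPM at most. B cell markers reached 44.8 CPM, for Blnk in WT with DMSO, and T cell markers 4.09 CPM, for Lck in WT with DMSO. Hdc, which encodes the enzyme that makes histamine and stands on the mast cell list, had 5.2 CPM in WT with DMSO and a log2 fold change of -3.77 with isorhamnetin. Fibroblast markers reached 1.82 CPM for Acta2, erythroid and megakaryocyte markers 0.374 CPM for Itga2b, and epithelial markers 0.0855 CPM for Krt5.

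Fold changes between the lines clustered by chromosome, for which a difference in chromosome copy number is a candidate explanation. It predicts chromosomes outside shuffled positions the same way under both treatments, and 2 were found, 1 in each line. These were chromosome 17 in GATA3-KO and chromosome 1 in Rictor-KO, the latter with medians of -0.102 and -0.09. At most 1 had been set as too few, so the prediction was met only with both lines counted together. Chromosome 1 also stood at -0.11 in GATA3-KO under DMSO, where shuffled positions reached -0.074, so its small shift under DMSO was not particular to Rictor-KO. On chromosome 17, 79.6% of genes stood above 0 in GATA3-KO, against 48.7% of other genes, and 14 of 16 runs of 40 genes had a median over 0.35, against 1 of 271 elsewhere. The last 2 runs, from 71.6 to 94.8 Mb, stood above WT in Rictor-KO too, with medians of 0.38 and 0.58 under DMSO and 0.51 and 0.52 under isorhamnetin. That end of the chromosome is thus not particular to GATA3-KO. No DNA was measured.

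Intron reads, a proxy for unspliced RNA, were tested for whether the fall of inflammatory genes in WT lies at transcription. Over 28 called inflammatory genes the median intron log2 fold change was -1.85, against -2.21 for exons, and 22 were lower, which is consistent with a change in transcription. For interferon-stimulated genes the intron median was -2.69 against -2.74, and for NRF2 targets 0.92 against 1.04.

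Of 100 regroupings of treatments within genotypes, drawn from 108 possible, 1 gave as many genes as the real grouping, which is the real one itself. The real grouping called 4292 genes for isorhamnetin averaged over genotypes, and the highest of the others called 4051. The real grouping thus ranked first among these draws, by a small margin. As the replicates may be technical, this ranking cannot tell the treatment from differences between cultures. Some regroupings leave the treatment intact in part of the genotypes.

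In Rictor-KO, 67 of 7839 genes with a mean of at least 16 CPM differed over 2-fold between the replicates under DMSO, and 56 of these differed the same way between the replicates under isorhamnetin. The numbers were 1 in GATA3-KO and 0 in WT under DMSO.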
